A study of Escherichia coli BW25113 with 24 samples.

How the data were processed

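Total RNA of Escherichia coli K-12 BW25113 was sequenced in 24 libraries, 3 in each of 8 groups, and every group was taken from the strain, plasmid and induction labels of its samples. Per the submitters' growth and treatment notes, cultures were kept in rich defined medium with ampicillin to mid-log phase. Uninduced samples were taken first, and induced samples 5 min after IPTG at 1 mM. Per the submitters' extraction notes, RNA was Trizol-extracted, fragmented by alkali, ligated to barcoded adapters, depleted of ribosomal RNA after pooling, and sequenced on a NextSeq500.

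Raw counts per locus tag were deposited in 1 table that held the 24 libraries, and the values were whole numbers. Per the submitters' processing notes, the genome build was ASM584v2 and the tools were STAR and DESeq2 1.22.2, with no role stated for either. The strandedness of counting was not given in the sources used here, so counts of genes that overlap or lie antisense to another gene, such as sibA and sokB, are uncertain, as are those of close paralogs such as tufA and tufB. The authors also deposited 7 comparison tables, each with a log2 fold change and its standard error per gene. The deposited tables gave a Wald p-value and an adjusted p-value per gene, named in the column style of DESeq2.

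The count table listed 4596 locus tags, of which 156 were empty in every library and 4440 held values, 8 of these with a total of 0. Names, gene classes and coordinates came from a reference gene table of the same assembly, which matched 4422 locus tags and left 18 unmatched. The low-count filter of edgeR (filterByExpr over the 8 groups, minimum count 10, minimum total 15) left 4203 genes. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, 1 mean per group and all 24 libraries in 1 fit. It had 16 residual degrees of freedom and a common dispersion of 0.0322. Totals of 261530 to 1958999 counts per library, mostly from tRNA genes, gave a median 95% half-width of 0.55 for a log2 change between 2 groups and 0.79 for the strain difference in the relA* response. Each comparison was a contrast of group means, p-values were adjusted by the Benjamini-Hochberg method over the 4203 genes within that comparison, and a gene was called at an adjusted p below 0.05. The standard error of a log2 change was its size divided by the square root of F. Levels are CPM on TMM-scaled library sizes, as mean ± SD with n = 3 libraries. The labels do not state whether replicates were separate cultures, so p-values measure the spread between samples.

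Lists of genes were written down with 29 names and 560 members, all present in the table. Each list was tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over the 29 lists, and again with a correlation estimated from the libraries. Counts of called members are over all tested genes, and beside them stands the count with p-values adjusted over the list alone. The lists covered ribosomal proteins, translation factors, ribosome assembly with RNA modification, aminoacyl-tRNA synthetases, RNA polymerase with core transcription factors, and 7 routes of amino acid synthesis. They also covered purine synthesis, pyrimidine synthesis, the RpoS regulon, ribosome hibernation with universal stress proteins, flagella with chemotaxis, ATP synthase, NADH dehydrogenase with cytochrome oxidases, and the tricarboxylic acid cycle. The remaining lists held DNA replication, fatty acid and phospholipid synthesis, cell wall with division, heat shock, the sigma E regulon, the Rcs regulon, iron uptake, cold shock and the lac operon.

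Choices made before the data were examined were the groups, 10 comparisons, the main test, the lists, the rule for named genes and the alternatives, except where the text says that a choice came later. The rule named, for each of 4 main comparisons, the 7 largest rises and the 7 largest falls. They were taken among called genes with a mean of at least 20 CPM whose libraries did not overlap between the compared groups, leaving out rRNA and tRNA genes. No overlap rule applied to differences between responses. Chance gives 10% of genes without overlap for 3 libraries against 3. The rule added up to 3 members of each called list, always named relA, rpoB, rpoS, dksA, spoT, rmf, uspA and thrA, and took 3 genes each way in the other comparisons. Genes of the lac operon and rlmD were named as checks.

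The test was run on simulated counts that kept the group sizes and depths of these libraries and changed 200 genes. With 4119 genes run for the wild-type induction comparison it recovered 64% of 2-fold and 95.9% of 4-fold changes, with 3.09% false among its calls. For the strain difference in that response the shares were 22% and 78.8%, with 1.96% false, and for the strain comparison before induction 62% and 99.0%, with 4.76% false. The 1 list moved in each simulation was recovered, and 0 of the 28 other lists were called. These lists were random genes simulated independently of each other, so false calls of lists whose members vary together were not tested. The simulation took the spread of each gene from the trend over genes. It held no spread shared by genes, such as the tRNA share. The recovered and false shares may therefore not hold for these libraries.

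Replicate numbers 0, 1 and 2 recur in every group. Per the submitters' notes the uninduced sample was taken before IPTG was added, but no label ties a replicate number to a culture or a day. Deviations from group means were correlated between same-numbered libraries, and numbers were taken to pair a comparison when all 3 correlations were above 0.1. This held for the relA- response of wild type (0.42, 0.39 and 0.25), the relA- response of P153L (0.50, 0.22 and 0.46) and the strain comparison with the relA* plasmid (0.18, 0.20 and 0.53). Over all comparisons, 9 of 12 induction pairs and 8 of 12 pairs between cultures were above 0.1. The tRNA share of counts followed the replicate number within each plasmid. It was 68.7 to 70.7% in replicate 0 of every relA- group, against 56.0 to 63.7% in replicates 1 and 2. In every relA* group it was highest in replicate 1 (70.8 to 72.7%). Numbers that the rule did not pair may therefore still share a source of spread, which the main fit leaves in its error. A fit with the replicate number as a block was run throughout. Its values stand beside the result where the numbers paired the samples and a count moved by more than 1.5 times, and otherwise in the closing section.

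The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no low-count filter, only the compared groups in the fit, the replicate block, rRNA and tRNA genes removed before scaling, a log2 change of at least 1 in addition, and each replicate left out in turn. For lists they were camera with an estimated correlation and fry, and for correlations across genes Spearman ranks, genes of at least 20 CPM, and the ribosomal protein and flagellar lists left out. The share of counts taken by tRNA genes as a covariate, a fit without the library of the lowest total, and 2 further comparisons of uninduced P153L libraries were chosen after seeing the data. No pair of replicate libraries was a duplicate, since their counts differed beyond counting error in 24 of 24 pairs. Read sequences, plasmid sequences and the genome sequence were not used here, so chromosomal and plasmid copies of a gene were not separated and no mutation was called.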

Results

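RNA from Escherichia coli K-12 BW25113 was sequenced to compare the response to (p)ppGpp, the nucleotide alarm signal of the stringent response, in wild type (CAG67202) and in a strain with RpoB-P153L (CAG68095). RpoB is the β subunit of RNA polymerase. Each strain carried pALS13, which expresses relA*, an active fragment of the (p)ppGpp synthetase RelA, or pALS14, which expresses an inactive fragment written relA-. Libraries were made before and 5 min after IPTG was added at 1 mM, which gave 8 groups with n = 3 each and 24 libraries. Total counts per library were 1031842 to 1348765 in uninduced and 261530 to 1601238 in induced wild type with relA-, and 704414 to 1346512 and 708770 to 1958999 with relA*. In P153L they were 509040 to 1373170 and 1095710 to 1730292 with relA-, and 664178 to 1726705 and 779710 to 1073611 with relA*. tRNA genes took 56.0 to 72.7% of counts and protein-coding genes 18.1 to 35.5%, and the median protein-coding gene had 7 to 78 counts. The tRNA share had means of 66.4 to 70.8% in the 4 relA* groups and 63.0 to 63.9% in the 4 relA- groups. Its SDs were 1.93 to 5.16 and 5.16 to 6.91 points. It also moved with the replicate number. Replicate 0 of the relA- groups had 68.7 to 70.7%, inside the range of the relA* libraries (61.7 to 72.7%), and replicates 1 and 2 had 56.0 to 63.7%. Of 4203 tested genes, 821 followed the tRNA share within groups. Changes are log2 ratios ± SE from edgeR, and levels are CPM as mean ± SD with n = 3 libraries.

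The induced gene was seen in every group. The gene relA (b2784, ASM584v2 chromosome, 2911417 to 2913651) rose in wild type by 5.41 ± 0.38 with the relA- plasmid (edgeR adjusted p = 1.27e-11) and by 5.71 ± 0.39 with the relA* plasmid (edgeR adjusted p = 4.59e-12). In P153L it rose by 5.84 ± 0.39 (edgeR adjusted p = 2.33e-12) and by 5.01 ± 0.37 (edgeR adjusted p = 2.68e-11). Its induced levels were 4606 ± 1502 and 6494 ± 200 CPM in wild type with relA- and relA*, and 15234 ± 3745 and 13307 ± 4673 CPM in P153L. The uninduced levels were 108 ± 1.59 and 124 ± 8.05 CPM in wild type and 267 ± 46.1 and 415 ± 131 CPM in P153L. The lowest induced library (3162 CPM) lay above the highest uninduced one (554 CPM). Its chromosomal neighbour rlmD (2913699 to 2915000), for an rRNA methyltransferase, rose by 3.44, 4.12, 4.83 and 4.54 in the same order. Chromosomal and plasmid reads of relA were not separated. The lacZ gene, listed beforehand among the deleted genes of BW25113 and named only as a check, stood at means of 90.6 to 118 CPM in the 8 groups. Its log2 changes after IPTG were −0.01 to 0.18, which do not show whether an intact lac operon would respond. The lac operon list was not called in wild type with relA* (median 0.08, limma camera adjusted p = 0.509). The rpoB gene stood at 310 ± 92.8 to 808 ± 160 CPM over the 8 groups.

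**Figure D1:**
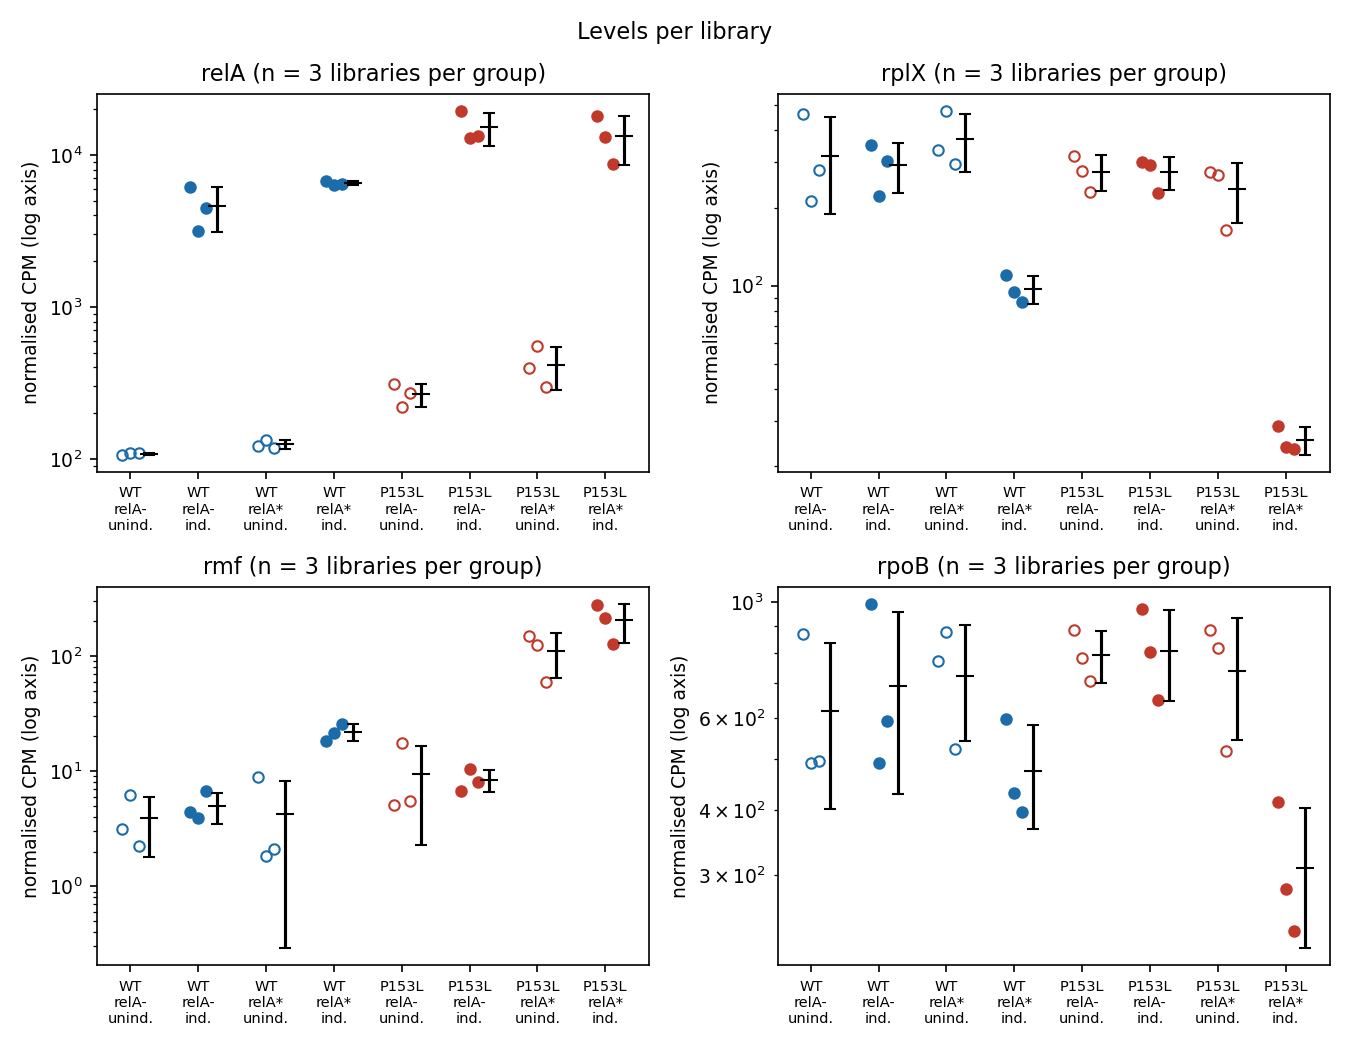
CPM on a log axis of relA, rplX, rmf and rpoB in each of the 24 libraries by group, with open points for uninduced and filled points for induced libraries, and the mean with SD bars beside each group of n = 3. In every induced library relA lay at 3162 CPM or more, and rplX lay lowest in induced P153L with relA*, at 25.3 ± 3.06 CPM.

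What relA* changed in wild type was asked by comparing induced with uninduced libraries that carried it. Genes of translation were 4 of the 7 largest falls that the naming rule gave. The initiation factor gene infA (b0884, 926225 to 926443) fell from 334 ± 80.5 to 36.6 ± 5.18 CPM (−3.16 ± 0.34, edgeR adjusted p = 1.09e-07). For rpsU, which encodes a protein of the small ribosomal subunit, the fall was from 654 ± 211 to 87.6 ± 4.61 CPM (−2.90 ± 0.37, edgeR adjusted p = 1.78e-06). The large-subunit genes rplA (−2.65 ± 0.30) and rplF (−2.39 ± 0.30) fell too, as did pyrL, the leader of the pyrimidine operon pyrBI (−3.07 ± 0.31, edgeR adjusted p = 3.23e-08). The primosome gene priB fell by 2.55 on the log2 scale and the putrescine importer gene plaP by 2.40. Besides relA and rlmD, the largest rises were rmf (b0953, 1015715 to 1015882), whose product dimerises and silences ribosomes (2.51 ± 0.62, edgeR adjusted p = 0.0146), and the manganese-linked small gene mntS (2.19 ± 0.33, edgeR adjusted p = 4.02e-05). The rmf rise rests on few counts, 1 to 6 in these uninduced and 12 to 34 in these induced libraries. Its mean passed 20 CPM through P153L libraries with relA* (59.1 to 277 CPM). Next came the leader ilvL of the isoleucine-valine operon (1.83 ± 0.32), the antitoxin RNA sibA (1.74 ± 0.32) and raiA, for another ribosome-binding stress factor (1.72 ± 0.40, edgeR adjusted p = 0.00769). The general stress sigma factor gene rpoS rose by 0.86 ± 0.23 (edgeR adjusted p = 0.0246). No call was made for dksA (−0.39 ± 0.29, edgeR adjusted p = 0.737), spoT (−0.18 ± 0.19), thrA (0.25 ± 0.22) or rpoB (−0.61 ± 0.30, edgeR adjusted p = 0.429).

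By list, 39 of 54 ribosomal protein genes fell in wild type (47 adjusted over the list alone), with a median of −1.40 and among them rplU at −2.16 ± 0.27. The list was called lower by camera of limma (adjusted p = 1.45e-58, and adjusted p = 0.0986 with an estimated correlation). Of 28 genes of ribosome assembly and RNA modification 5 fell (8 adjusted over the list alone), with a median of −0.37, among them rimM (−2.15 ± 0.32), trmD (−1.51 ± 0.25) and obgE (−1.03 ± 0.22). For this list camera of limma gave adjusted p = 2.73e-06 (adjusted p = 0.0986 with an estimated correlation). Translation factors had a median of −0.55 and 3 of 13 fell (7 adjusted over the list alone), with efp at −0.99 ± 0.26 and lepA at −0.76 ± 0.22. Their call by camera of limma had adjusted p = 2.73e-06 (adjusted p = 0.296 with an estimated correlation). In the RNA polymerase list 3 of 13 fell (3 adjusted over the list alone), nusG (−1.31 ± 0.29), rpoA (−1.33 ± 0.35) and rpsJ (−1.38 ± 0.35), which also encodes a ribosomal protein. The list had a median of −0.30 and a limma camera adjusted p = 0.00671 (adjusted p = 0.507 with an estimated correlation). DNA replication genes had a median of −0.35, and priB and the primase gene dnaG (−1.15 ± 0.21) were the 2 of 22 that fell (2 adjusted over the list alone). That list was called by camera of limma at adjusted p = 4.49e-05 (adjusted p = 0.0986 with an estimated correlation).

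The ATP synthase list was called lower in wild type at a median of −0.46 with 0 of 9 members called by edgeR (1 adjusted over the list alone), atpH lying nearest at −0.78 ± 0.25. The call of camera of limma had adjusted p = 0.00211 (adjusted p = 0.438 with an estimated correlation). Fatty acid and phospholipid synthesis had a median of −0.25 with 0 of 22 called by edgeR (3 adjusted over the list alone), fabA at −0.81 ± 0.26, and a limma camera adjusted p = 0.00671 (adjusted p = 0.454 with an estimated correlation). Ribosome hibernation and universal stress genes were called higher, with a median of 0.48 and rmf, raiA and uspA (1.48 ± 0.28) as the 3 of 10 that rose (3 adjusted over the list alone). Its test by camera of limma gave adjusted p = 0.00522 (adjusted p = 0.121 with an estimated correlation). Synthesis of glutamate, proline, serine and cysteine was called higher at a median of 0.15, with cysK (1.23 ± 0.27) and serA (0.83 ± 0.22) as the 2 of 14 that rose (2 adjusted over the list alone). Here camera of limma gave adjusted p = 0.0203 (adjusted p = 0.296 with an estimated correlation). The other 20 lists were not called, with limma camera adjusted p from 0.066 to 0.98. Among them, medians were −0.08 for aminoacyl-tRNA synthetases, −0.06 for histidine, 0.09 for branched-chain, 0.01 for aromatic, 0.26 for threonine and lysine, −0.20 for methionine and −0.02 for arginine synthesis, whose mean was 0.03. They were −0.16 for purine and −0.12 for pyrimidine synthesis, 0.09 for the RpoS regulon, −0.09 for flagella, 0.07 for the tricarboxylic acid cycle, −0.04 for the cell wall and 0.14 for heat shock. The sigma E and Rcs regulons both had −0.06, iron uptake −0.04 and cold shock −0.31, and NADH dehydrogenase with cytochrome oxidases had a median of 0.0029 and a mean of −0.07.

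In all, edgeR called 45 genes higher and 91 lower in wild type after relA* induction, 34 and 77 of them by at least 1 on the log2 scale. DESeq2 called 32 and 87, sharing 114. Higher calls numbered 24 without relA* induced replicate 2, and 29 and 21 without uninduced replicates 1 and 2, while lower calls numbered 60 and 59 without induced replicates 1 and 2. Of the named genes, rmf, raiA, rpoS, serA, efp, lepA, nusG, rpsJ and rpoA missed the edgeR threshold without at least 1 of the 6 libraries. Their highest edgeR adjusted p were 0.172, 0.112, 0.124, 0.11, 0.129, 0.258, 0.0541, 0.135 and 0.168 in that order, and DESeq2 gave lepA an adjusted p of 0.0762. The call of the RNA polymerase list was lost without induced replicate 2 or uninduced replicate 1 (limma camera adjusted p = 0.0843 and 0.0929). Glutamate to cysteine synthesis lost its call without induced replicate 0 or uninduced replicate 1 (limma camera adjusted p = 0.0973 and 0.0782). With fry the lists of translation factors, RNA polymerase, ATP synthase and fatty acid synthesis lost theirs.

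The same induction in P153L asked how that strain responds. Levels of rpsU fell from 373 ± 124 to 24.7 ± 15.0 CPM (−4.00 ± 0.42, edgeR adjusted p = 7.17e-08) and infA to 12.6 ± 3.15 CPM (−3.62 ± 0.42, edgeR adjusted p = 3.38e-07). The other largest falls were ribosomal protein genes, rpsN (−3.26 ± 0.39), rplX (−3.22 ± 0.31, from 236 ± 61.4 to 25.3 ± 3.06 CPM), rplU (−3.04 ± 0.32), rplW (−2.96 ± 0.33) and rplD (−2.91 ± 0.37). The rpoB gene itself fell from 740 ± 195 to 310 ± 92.8 CPM (−1.26 ± 0.30, edgeR adjusted p = 0.00806). Besides relA and rlmD, the largest rises were ybeU, of unknown function (2.88 ± 0.24, edgeR adjusted p = 3e-10), and mntS (1.52 ± 0.23). Then came the formate dehydrogenase gene fdhF (1.43 ± 0.20), the electron transfer flavoprotein gene fixB (1.10 ± 0.30, edgeR adjusted p = 0.0229) and entB of siderophore synthesis (0.97 ± 0.23). Of these ybeU, fdhF and entB rose in P153L with the relA- plasmid too. The rise of rmf was 0.93 ± 0.28 (edgeR adjusted p = 0.0482), while rpoS (−0.25 ± 0.21, edgeR adjusted p = 0.633), uspA (−0.16 ± 0.29), dksA (−0.22 ± 0.32), spoT (−0.30 ± 0.20) and thrA (−0.53 ± 0.22) did not pass. In these uninduced libraries rpoS already stood at 177 to 284 CPM, against 63.3 to 71.3 in uninduced and 105 to 144 in induced wild type with relA*. For uspA the values were 30.5 to 61.3 CPM, against 21.9 to 25.3 and 61.9 to 73.6. Levels of rmf and thrA were also higher before induction than in wild type, and those of dksA and spoT were not.

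In P153L, 46 of 54 ribosomal protein genes fell (51 adjusted over the list alone), with a median of −1.99 (limma camera adjusted p = 6.14e-62, and adjusted p = 0.0861 with an estimated correlation). Translation factors had a median of −0.79 with 6 of 13 lower (11 adjusted over the list alone), including tufB (−2.12 ± 0.43) and efp (−1.77 ± 0.35). On these camera of limma gave adjusted p = 1.88e-08 (adjusted p = 0.155 with an estimated correlation). Of 23 aminoacyl-tRNA synthetase genes 8 fell (12 adjusted over the list alone), with a median of −0.46, among them asnS (−2.12 ± 0.26), alaS (−1.37 ± 0.20) and valS (−1.20 ± 0.23). The synthetases had a limma camera result of adjusted p = 4.93e-08 (adjusted p = 0.169 with an estimated correlation). The RNA polymerase list had a median of −0.67 with 5 of 13 lower (6 adjusted over the list alone), among them rpoB, nusG (−2.30 ± 0.36) and rpsJ (−2.55 ± 0.40). In limma camera it had adjusted p = 2.19e-05 (adjusted p = 0.169 with an estimated correlation). Ribosome assembly and RNA modification had a median of −0.27 with 3 of 28 lower (3 adjusted over the list alone), rimM (−2.04 ± 0.35), trmD (−1.04 ± 0.26) and rimO (−1.03 ± 0.28). Its limma camera test gave adjusted p = 0.00103 (adjusted p = 0.155 with an estimated correlation). Branched-chain amino acid synthesis had a median of −0.39 with 4 of 13 lower (4 adjusted over the list alone), among them leuA (−1.08 ± 0.22), leuB (−0.94 ± 0.22) and ilvA (−0.93 ± 0.22). This route was called by camera of limma at adjusted p = 0.00252 (adjusted p = 0.155 with an estimated correlation).

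Parts of 3 lists of energy and lipid genes fell in P153L as well. In the ATP synthase list 5 of 9 genes fell (6 adjusted over the list alone, and 1 higher), with a median of −0.88 and atpF (−1.47 ± 0.29), atpH (−1.26 ± 0.27) and atpB (−0.88 ± 0.20) among them. Its call by camera of limma had adjusted p = 0.00033 (adjusted p = 0.179 with an estimated correlation). NADH dehydrogenase and cytochrome oxidases had a median of −0.51 with 7 of 20 lower (10 adjusted over the list alone), among them cyoA (−1.50 ± 0.32), nuoG (−1.11 ± 0.26) and nuoH (−0.93 ± 0.23). As a list they reached in limma camera an adjusted p = 9.18e-06 (adjusted p = 0.228 with an estimated correlation). Of 22 fatty acid and phospholipid genes 6 fell (10 adjusted over the list alone), with a median of −0.65, among them fabB (−1.99 ± 0.30), fabA (−1.66 ± 0.31) and accB (−1.47 ± 0.32). Lipid synthesis was called by limma camera at adjusted p = 8.39e-08 (adjusted p = 0.104 with an estimated correlation). DNA replication had a median of −0.46 with 5 of 22 lower (8 adjusted over the list alone), among them dnaG (−1.47 ± 0.22), dnaA (−1.32 ± 0.24) and holC (−1.89 ± 0.36). Replication was called by limma camera at adjusted p = 8.2e-07 (adjusted p = 0.0861 with an estimated correlation). The sigma E regulon of the envelope had a median of −0.60 with 4 of 16 lower (8 adjusted over the list alone), among them fkpA (−1.17 ± 0.25), surA (−1.10 ± 0.27) and skp (−0.96 ± 0.26). This regulon was called by limma camera at adjusted p = 2.54e-05 (adjusted p = 0.104 with an estimated correlation). The RpoS regulon was called higher at a median of 0.14 with 0 of 37 members called by edgeR (0 adjusted over the list alone), osmE lying nearest at 0.93 ± 0.34. That call had a limma camera adjusted p = 0.0274 (adjusted p = 0.17 with an estimated correlation), and was lost without relA* induced replicate 0 or uninduced replicate 2 (adjusted p = 0.22 and 0.103). It was also lost without the low-count filter, with fry, and with the tRNA share as a covariate, a fit chosen after seeing the data. The other 17 lists were not called (limma camera adjusted p from 0.0521 to 0.823).

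In P153L edgeR called 16 genes higher and 187 lower after relA* induction, 8 and 147 of them by at least 1 on the log2 scale. DESeq2 called 10 and 173, sharing 177. Higher calls numbered 10 and 39 without uninduced replicates 1 and 2, and lower calls 99 without induced replicate 2 and 115 and 295 without uninduced replicates 0 and 2. The genes fixB, rmf, rimO, skp and rpoB missed the edgeR threshold without at least 1 library (adjusted p up to 0.238, 0.257, 0.106, 0.272 and 0.0855). With only the compared groups in the fit fixB, rmf, rimO and skp missed it, with DESeq2 fixB and rmf did, and rmf also with the tRNA share as a covariate. So did trmD, ilvA, leuB, nuoG, nuoH, cyoA, accB and surA without induced replicate 2, and some of them without induced replicate 1 or uninduced replicates 0 or 1.

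**Figure D2:**
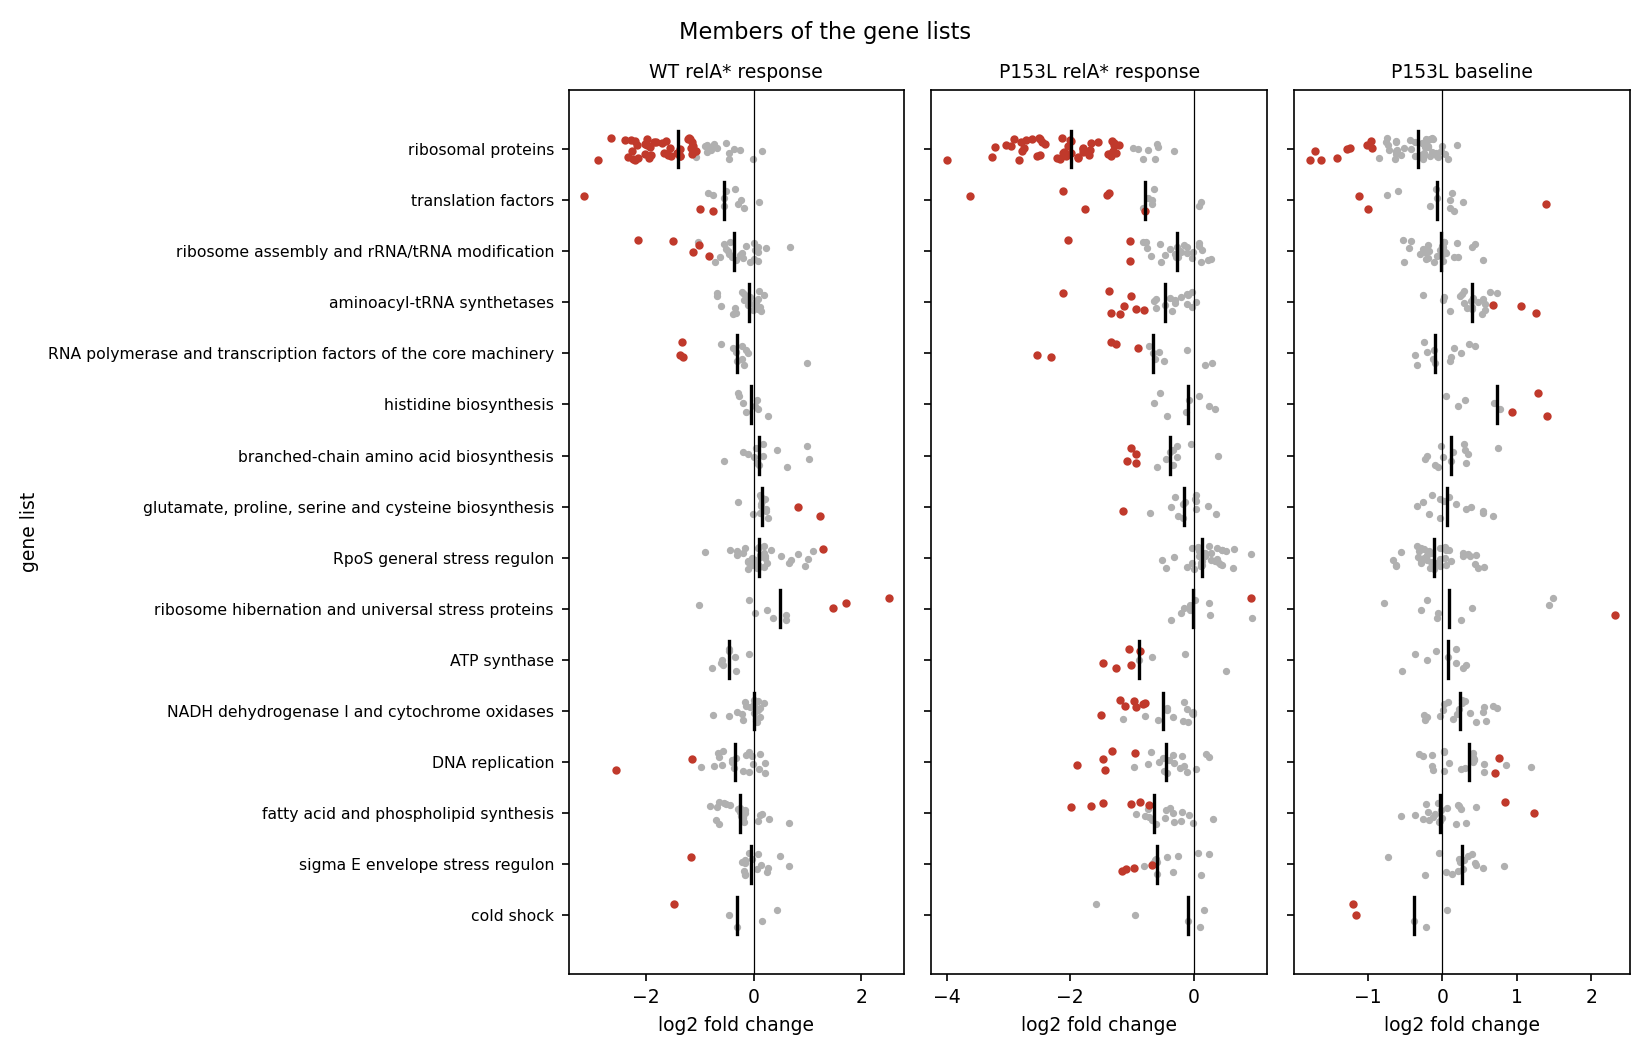
Log2 fold change of each member of the lists called in any of 3 comparisons, the relA* response of wild type, that of P153L, and P153L against wild type before induction with the relA- plasmid. Red points passed an edgeR adjusted p of 0.05, grey points did not, and black bars are list medians, which for ribosomal proteins lay at −1.40, −1.99 and −0.33.

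Whether the strains respond differently was tested as the difference between both responses. The gene tmaR (b2007, 2079032 to 2079361), for a pole protein that binds a sugar transport enzyme, rose in wild type (1.20 ± 0.30) and fell in P153L (−1.55 ± 0.29), a difference of −2.75 ± 0.42 (edgeR adjusted p = 0.001). The pantothenate gene panD differed by −2.32 ± 0.43 (edgeR adjusted p = 0.00876), with −0.02 ± 0.27 in wild type and −2.34 ± 0.32 in P153L. For gnsB the difference was −1.93 ± 0.36 (edgeR adjusted p = 0.00876), with a rise of 1.41 ± 0.27 in wild type and −0.52 ± 0.24 in P153L. The alanyl-tRNA synthetase gene alaS differed by −1.46 ± 0.28 (edgeR adjusted p = 0.00959), with 0.09 ± 0.19 and −1.37 ± 0.20. The methionine sulfoxide reductase gene msrC (−2.22 ± 0.44, edgeR adjusted p = 0.0163), the malate synthase gene aceB (−1.46 ± 0.31, edgeR adjusted p = 0.0319) and ytfP (−1.93 ± 0.43, edgeR adjusted p = 0.0496) differed in the same direction. No difference was called for uspA (−1.64 ± 0.40, edgeR adjusted p = 0.0785), rpoS (−1.11 ± 0.31, edgeR adjusted p = 0.115), rmf (−1.58 ± 0.71, edgeR adjusted p = 0.449), rpoB (−0.65 ± 0.42), thrA (−0.78 ± 0.31), spoT (−0.12 ± 0.27), dksA (0.17 ± 0.43) or relA (−0.70 ± 0.46). The level of relA was not equal, since with the relA* plasmid it was higher in uninduced P153L than in uninduced wild type (1.73 ± 0.34). After induction its lowest P153L library (8727 CPM) lay above its highest wild-type library (6723 CPM). The strain difference therefore cannot separate the strain from its level of relA. For each of these genes the uninduced libraries also enter the difference, so another starting level and another response are not told apart. Levels of rpoS, uspA and rmf were already higher in uninduced P153L with relA* than in uninduced wild type.

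As lists, 10 were called in the strain difference by camera, and each call was lost with an estimated correlation. Ribosomal proteins had a median of −0.51 with 0 of 54 called by edgeR (4 adjusted over the list alone), rplW lying nearest at −1.83 ± 0.43 (limma camera adjusted p = 0.00019, and adjusted p = 0.63 with an estimated correlation). Branched-chain synthesis had −0.77 with 0 called by edgeR (6 adjusted over the list alone) and ilvN at −1.26 ± 0.42 (limma camera adjusted p = 0.00051, and adjusted p = 0.215 with an estimated correlation). The threonine and lysine list had −0.66 with 0 called (0 adjusted over the list alone) and dapA at −1.07 ± 0.34 (limma camera adjusted p = 0.00109, and adjusted p = 0.215 with an estimated correlation). Glutamate, proline, serine and cysteine synthesis had −0.26 with 0 called (3 adjusted over the list alone) and cysK at −1.48 ± 0.34 (limma camera adjusted p = 0.00248, and adjusted p = 0.215 with an estimated correlation). Aminoacyl-tRNA synthetases had −0.34 with alaS called of 23 (3 adjusted over the list alone) and asnS at −1.44 ± 0.35 (limma camera adjusted p = 0.00027, and adjusted p = 0.456 with an estimated correlation). NADH dehydrogenase and cytochrome oxidases had −0.48 with 0 called (0 adjusted over the list alone) and nuoB at −1.04 ± 0.34 (limma camera adjusted p = 0.00107, and adjusted p = 0.489 with an estimated correlation). Fatty acid and phospholipid synthesis had −0.28 with 0 called (0 adjusted over the list alone) and fabB at −1.30 ± 0.41 (limma camera adjusted p = 0.00477, and adjusted p = 0.456 with an estimated correlation). Heat shock genes had −0.52 with 0 called (2 adjusted over the list alone) and rpoH at −1.62 ± 0.44 (limma camera adjusted p = 0.00541, and adjusted p = 0.456 with an estimated correlation). The sigma E regulon had −0.53 with 0 called (5 adjusted over the list alone) and skp at −1.22 ± 0.37 (limma camera adjusted p = 0.00135, and adjusted p = 0.261 with an estimated correlation). Flagella and chemotaxis had a median of 0.24 with 0 called (1 lower adjusted over the list alone) and flgG at 1.44 ± 0.60 (limma camera adjusted p = 0.0112, and adjusted p = 0.456 with an estimated correlation). Before induction with the relA* plasmid, camera called the branched-chain, threonine and lysine, glutamate to cysteine and NADH dehydrogenase lists higher in P153L than in wild type. It called ribosomal proteins lower there. Those uninduced libraries enter this difference, so another starting level and another response are not told apart.

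For the strain difference edgeR called 0 genes higher and 7 lower, with 411 genes at an unadjusted p below 0.05 where chance gives 210. DESeq2 called 0 higher and 17 lower, sharing 3. It gave no adjusted p for tmaR, panD, msrC and ytfP, so their calls were neither kept nor lost there. Lower calls numbered 34, 4 and 1 without P153L induced replicates 0, 1 and 2, 3 and 97 without P153L uninduced replicates 0 and 2, and 4 without wild-type induced replicate 1 or 2 or wild-type uninduced replicate 0. Without P153L uninduced replicate 2, 7 genes were called higher. Both uspA and rpoS passed without P153L induced replicate 0 or uninduced replicate 2. With the tRNA share as a covariate, a fit chosen after seeing the data, edgeR called 4 higher and 109 lower, uspA, rpoS and thrA among the latter. Only tmaR of the 7 passed without each library in turn, while panD, gnsB and alaS reached an edgeR adjusted p of 0.0739, 0.0552 and 0.0795, and msrC, aceB and ytfP of 0.137, 0.178 and 0.197.

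Of the 10 lists, 5 lost their call in the strain difference without 1 library. Without P153L induced replicate 2 these were ribosomal proteins, flagella, NADH dehydrogenase and heat shock, and without wild-type uninduced replicate 2 ribosomal proteins, flagella, fatty acid synthesis and heat shock (limma camera adjusted p from 0.0526 to 0.0755). Flagella also lost it without P153L uninduced replicate 1 (limma camera adjusted p = 0.055). With fry these 5 and the aminoacyl-tRNA synthetases lost theirs.

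Across genes, most of the wild-type falls were also called in P153L and few of the wild-type rises were. Over 4201 genes without relA and rlmD the responses had r = 0.424 and a slope of 0.476 (Spearman rho 0.176), and genes are not independent replicates. Of 91 genes lower in wild type and 187 in P153L, 63 were lower in both, among them infA, rpsU and rplU, where 4.05 are expected by chance. Of 43 higher in wild type and 14 in P153L, 5 were higher in both, where 0.143 are expected, and tmaR was called in opposite directions. The 5 were mntS, ybfA (named after its values were seen), rmf, whose P153L call was lost under other settings as said above, and ybeU and fdhF, which rose in P153L with the relA- plasmid too. The 91 wild-type fallers had a median of −1.47 there and −1.80 in P153L, with 90 of the same sign, while the 43 risers had 1.21 there and 0.01 in P153L, with 23 of the same sign. The 14 P153L risers had a median of 0.47 in wild type, with 12 of the same sign. Before induction the 43 wild-type risers already stood higher in P153L with the relA* plasmid than with the relA- plasmid, by a median of 0.85 with 39 above 0, in libraries that the P153L response shares.

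**Figure D3:**
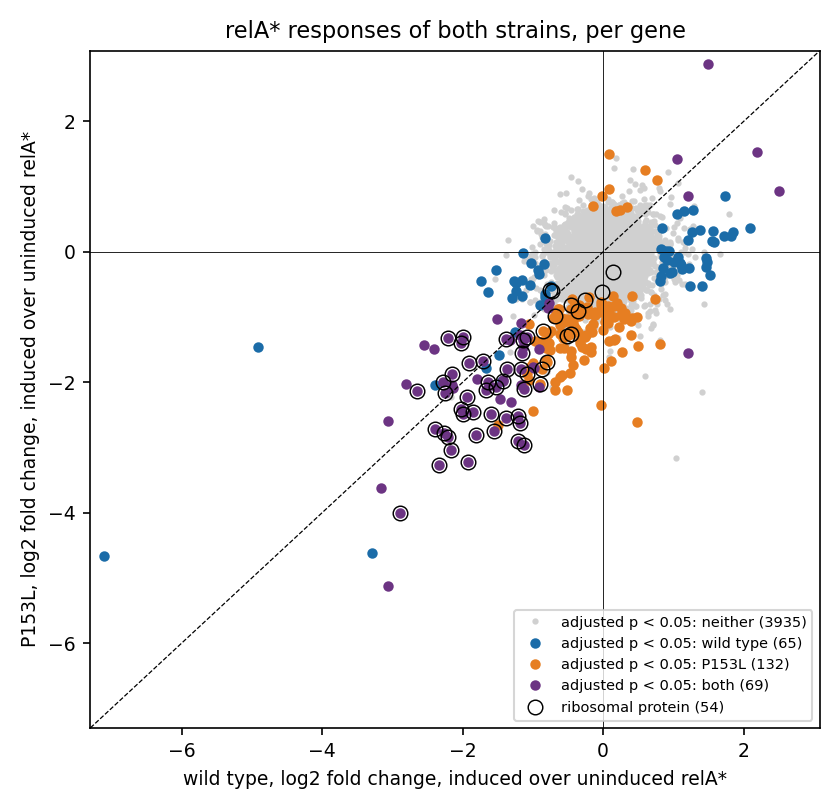
Log2 fold change of 4201 genes after relA* induction in wild type (horizontal) and P153L (vertical), without relA and rlmD, coloured by the strain in which edgeR called the gene. Ribosomal protein genes are ringed, and 63 genes were called lower in both strains.

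The controls asked what induction did with the inactive fragment. In wild type relA, rlmD and ybeU (1.56 ± 0.23, edgeR adjusted p = 0.000174) rose. In all edgeR called 3 higher and 0 lower with 107 genes at an unadjusted p below 0.05 where chance gives 210, and DESeq2 called 3 and 0. With the replicate number as a block edgeR called 4 and 2. In P153L edgeR called 8 higher and 0 lower with 122 genes at an unadjusted p below 0.05, and DESeq2 called 7 and 0. They were relA, rlmD and ybeU (2.55 ± 0.22, edgeR adjusted p = 1.29e-09) and 5 genes named after their values were seen, garL (1.47 ± 0.25), lptE (1.31 ± 0.29), fdhF (1.23 ± 0.20), entB (1.19 ± 0.21) and atpI (1.04 ± 0.20). Without uninduced replicate 1 there were 5. Of the lists, 0 of 29 were called in wild type (limma camera adjusted p from 0.097 to 0.989). In P153L the threonine and lysine list was called lower at a median of −0.16 with 0 of 15 members called (0 adjusted over the list alone), with limma camera adjusted p = 0.00728 (adjusted p = 0.697 with an estimated correlation), a call lost without replicate 0 of either state and with fry.

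The part of the response that the inactive fragment lacked was tested as the relA* response minus the relA- response. In wild type raiA stood 2.86 ± 0.59 higher (edgeR adjusted p = 0.00863). This was more than its relA* response alone, since raiA also fell, without a call, after relA- induction. The attenuator leaders pheL (2.21 ± 0.55, edgeR adjusted p = 0.0439) and hisL (2.06 ± 0.51, edgeR adjusted p = 0.0423) followed. Lower stood pyrL (−3.11 ± 0.39), infA (−2.88 ± 0.45) and priB (−2.59 ± 0.36). In P153L mntS stood higher (1.83 ± 0.41, edgeR adjusted p = 0.00944), and rpsU (−3.50 ± 0.54), rpsN (−3.29 ± 0.48) and infA (−3.26 ± 0.53) lower. Ribosomal proteins had a median of −1.31 in wild type with 16 of 54 lower (39 adjusted over the list alone), with limma camera adjusted p = 2.65e-45 (adjusted p = 0.228 with an estimated correlation). In P153L they had a mean of −1.95 with 35 lower (48 adjusted over the list alone), with limma camera adjusted p = 1.65e-65 (adjusted p = 0.141 with an estimated correlation). A median and a mean are unlike measures, so these values do not compare the strains. Of 9 lists called in wild type and 11 in P153L, 0 held with an estimated correlation, the adjusted p lying between 0.21 and 0.581 and between 0.141 and 0.415. With fry 0 of the 9 and 9 of the 11 were called. Without at least 1 library 4 of the 9 were lost, RNA polymerase, ATP synthase, branched-chain and threonine and lysine synthesis, and 1 of the 11, branched-chain synthesis. By edgeR 8 genes were higher and 26 lower in wild type (DESeq2 8 and 31, sharing 33), and 1 and 69 in P153L (DESeq2 1 and 79, sharing 68).

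Leaving out libraries moved these counts. In wild type the higher count was 2 without relA* induced replicates 1 or 2, uninduced replicates 0 or 1, or relA- induced replicates 1 or 2, was 4 without relA* uninduced replicate 2, and was 0 without relA- uninduced replicate 2, where raiA, pheL and hisL all missed the edgeR threshold. The lower count was 10 and 16 without relA* induced replicates 1 and 2, 13 without relA* uninduced replicate 1, and 50, 16 and 12 without relA- uninduced replicates 0, 1 and 2. In P153L it was 37 without relA* induced replicate 2 and 142 without relA* uninduced replicate 2. The higher count was 3 and 2 without relA* induced replicates 0 and 1, 5 without relA* uninduced replicate 2, and 0 without relA- uninduced replicate 1, where mntS missed.

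The strains were compared before induction in uninduced libraries with the relA- plasmid, P153L against wild type. The small RNA fnrS (b4699, 1409129 to 1409250), which the anaerobic regulator FNR activates, stood at 558 ± 158 CPM against 4.99 ± 1.09 in wild type (6.76 ± 0.46, edgeR adjusted p = 3.7e-12). The Rac prophage genes racC (3.98 ± 0.31) and ydaS (3.12 ± 0.31), the small gene yncL (3.66 ± 0.42), the small RNAs mcaS (3.55 ± 0.34) and sokB (2.94 ± 0.34), and gnsB (2.82 ± 0.25) were the next highest. With the relA* plasmid the difference was 2.16 ± 0.55 for fnrS and 0.52 ± 0.50 for racC. Lowest were the division gene zapB (−2.04 ± 0.35, edgeR adjusted p = 0.000172) and the ribosomal protein genes rpsT (567 ± 240 against 1962 ± 756 CPM, −1.79 ± 0.37), rpmH (−1.71 ± 0.31), rpsU (−1.64 ± 0.34) and rpsO (−1.42 ± 0.29). With them lay the ribose gene rbsD (−1.65 ± 0.31) and the lipopolysaccharide ligase gene waaL (−1.54 ± 0.27). Both relA (1.30 ± 0.33, edgeR adjusted p = 0.0141) and rpoS (0.95 ± 0.22, edgeR adjusted p = 0.00604) were higher. No call was made for rpoB (0.36 ± 0.29, edgeR adjusted p = 0.674), rmf (1.48 ± 0.61, edgeR adjusted p = 0.21), uspA (0.40 ± 0.33), dksA (−0.57 ± 0.29), spoT (−0.13 ± 0.19) or thrA (0.09 ± 0.22). The lacI gene, for the repressor of the IPTG-responsive promoter, was higher by 2.13 ± 0.35.

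Histidine synthesis was called higher before induction in P153L, with a median of 0.74 and 3 of 8 genes called (5 adjusted over the list alone), hisI (1.41 ± 0.36), hisG (1.28 ± 0.33) and hisF (0.94 ± 0.22). The call held (limma camera adjusted p = 0.00013, and adjusted p = 0.0433 with an estimated correlation). Aminoacyl-tRNA synthetases had a median of 0.40 with 3 of 23 higher (9 adjusted over the list alone), tyrS (1.26 ± 0.23), pheS (1.06 ± 0.24) and metG (0.68 ± 0.17), with a limma camera adjusted p = 9.27e-07 (adjusted p = 0.399 with an estimated correlation). DNA replication had 0.35 with dnaE (0.76 ± 0.19) and nrdB (0.70 ± 0.18) as the 2 of 22 higher (4 adjusted over the list alone), and limma camera adjusted p = 0.0133 (adjusted p = 0.399 with an estimated correlation). Ribosomal proteins had −0.33 with 9 of 54 lower (14 adjusted over the list alone), and limma camera adjusted p = 2.26e-08 (adjusted p = 0.783 with an estimated correlation). Cold shock genes had −0.38 with cspA (−1.20 ± 0.32) and cspE (−1.17 ± 0.33) as the 2 of 5 lower (2 adjusted over the list alone), and limma camera adjusted p = 0.0241 (adjusted p = 0.399 with an estimated correlation). The other 24 lists were not called (limma camera adjusted p from 0.0581 to 0.932).

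With the relA- plasmid edgeR called 143 genes higher and 43 lower in uninduced P153L, 28 of the lower ones by at least 1 on the log2 scale, and DESeq2 called 116 and 37, sharing 150. The higher genes lay close together, 76 of 142 with a position inside the 500000 bases from 1243180 to 1743179 (ASM584v2), a window chosen after the data were examined, where 15.0 are expected from its 434 tested genes. It held fnrS, racC, ydaS, mcaS, sokB, yncL and gnsB. Lower calls numbered 27 and 16 without P153L replicates 1 and 2 and 25 without wild-type replicate 0, and relA and rpoS reached an edgeR adjusted p of 0.0721 and 0.0557 without 1 library. The cold shock call was lost without P153L replicate 2 or wild-type replicates 0 or 2, that of DNA replication without wild-type replicate 2 and that of ribosomal proteins without wild-type replicate 0 (limma camera adjusted p from 0.0604 to 0.104). Cold shock was also lost without the low-count filter, and with fry only histidine synthesis of the 5 lists held. The calls of cspA, cspE, dnaE, hisF, hisG, hisI, metG, nrdB and pheS were lost without at least 1 of the 6 libraries.

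**Figure D4:**
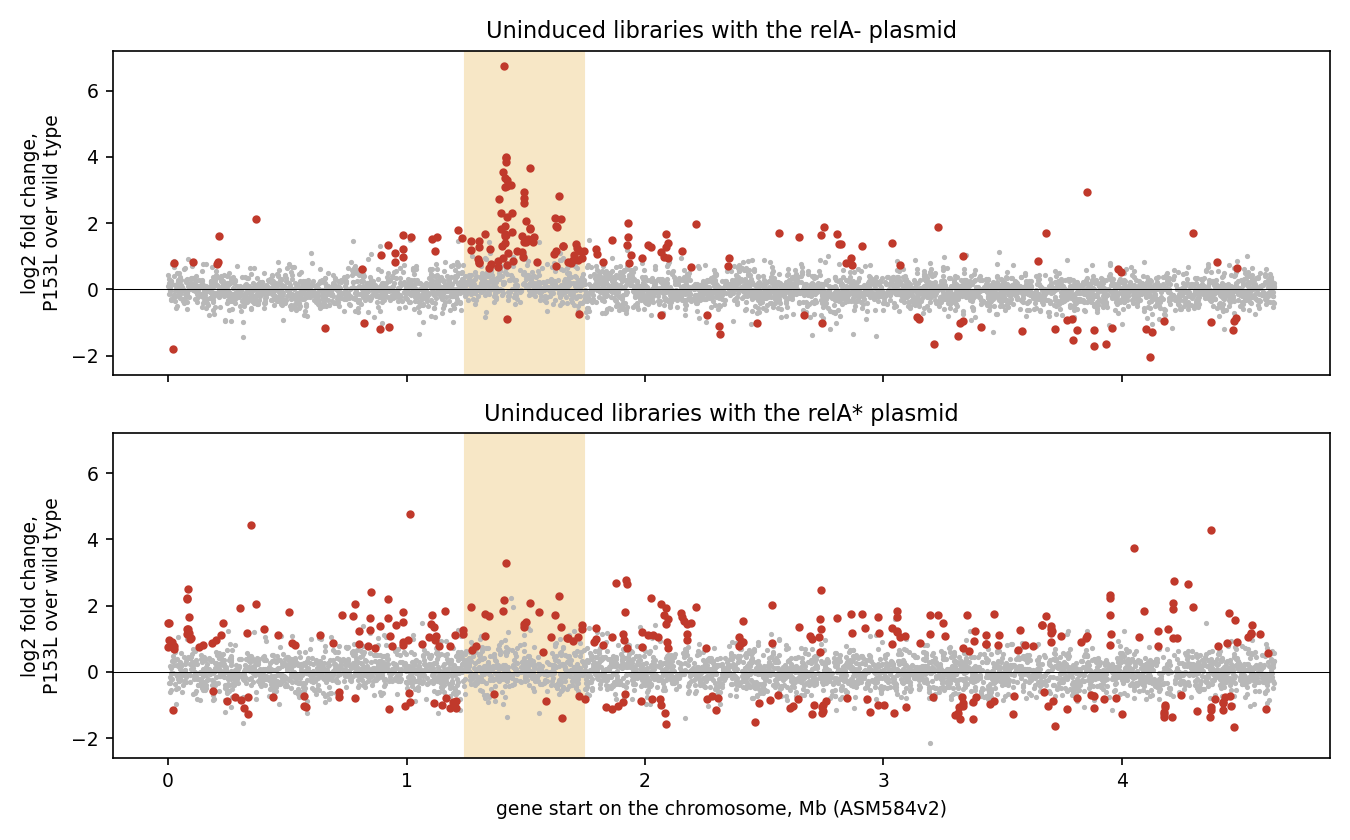
Log2 fold change of P153L over wild type in uninduced libraries against gene start on the chromosome (Mb, ASM584v2), with the relA- plasmid above and the relA* plasmid below. Red points passed an edgeR adjusted p of 0.05, and the shaded stretch of 500000 bases held 76 of the 142 genes called higher with the relA- plasmid, of which 15 were also called higher with the relA* plasmid.

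With the relA* plasmid the same strain comparison gave other leading genes. rmf stood at 111 ± 46.6 CPM in uninduced P153L against 4.26 ± 3.97 in wild type (4.76 ± 0.50, edgeR adjusted p = 6.67e-08), the entericidin gene ecnB at 137 ± 63.1 against 7.53 ± 4.14 CPM (4.28 ± 0.50). The RNA csrC (b4457, 4051036 to 4051281), which binds the regulator CsrA, stood at 1676 ± 549 against 125 ± 27.2 CPM (3.74 ± 0.33). Lowest were pyrL (−1.68 ± 0.26), cspA (−1.62 ± 0.36) and the protease adaptor gene sspB (−1.42 ± 0.28). With this plasmid relA was higher by 1.73 ± 0.34 (edgeR adjusted p = 0.00062) and lacI by 2.04 ± 0.36. Branched-chain amino acid synthesis was called higher with a median of 1.14 and 9 of 13 members called (9 adjusted over the list alone), among them leuD (2.23 ± 0.31). This call held (limma camera adjusted p = 1.38e-08, and adjusted p = 0.0192 with an estimated correlation). Ribosomal proteins had −0.78 with 16 of 54 lower (34 adjusted over the list alone), and limma camera adjusted p = 1.72e-14 (adjusted p = 0.393 with an estimated correlation). The threonine and lysine (median 0.61), histidine (0.61), glutamate to cysteine (0.39) and hibernation (0.81) lists were called higher, each at an adjusted p = 0.0613 with an estimated correlation in camera of limma. The aromatic (0.30), NADH dehydrogenase (0.47), ribosome assembly (−0.25) and cold shock (−0.92) lists were called at adjusted p = 0.0887, 0.642, 0.244 and 0.154 with an estimated correlation in camera of limma. Of these the aromatic call was lost without P153L replicates 0 or 1 or wild-type replicate 0, NADH dehydrogenase without P153L replicates 0 or 1 or wild-type replicate 2, and ribosome assembly without P153L replicate 2 or wild-type replicate 0 (limma camera adjusted p from 0.0506 to 0.307). The aromatic and ribosome assembly calls were also lost with the tRNA share as a covariate, a fit chosen after seeing the data, and cold shock without the low-count filter. NADH dehydrogenase was lost with fry and with only the compared groups, and ribosomal proteins with fry. In this comparison edgeR called 225 genes higher and 136 lower, or 286 and 212 with the replicate number as a block. DESeq2 called 179 and 113, sharing 283. Without P153L replicate 0 there were 143 and 73, and lower calls numbered 89 and 77 without wild-type replicates 0 and 1.

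In wild type the plasmids themselves were compared before induction. There relA differed by 0.20 ± 0.33, rmf by −0.01 ± 0.81, rpoS by 0.23 ± 0.23 and uspA by 0.69 ± 0.34. None was called, since edgeR had 0 genes higher and 0 lower, with 168 at an unadjusted p below 0.05 where chance gives 210, and DESeq2 had 0 and 0. The median 95% half-width of a log2 change was 0.53. Still, camera called 4 lists higher with 0 members called by edgeR (0 adjusted over the list alone), ribosomal proteins at 0.18, aminoacyl-tRNA synthetases at 0.21, histidine synthesis at 0.34 and DNA replication at 0.12. In camera of limma they had adjusted p = 0.828, 0.619, 0.291 and 0.515 with an estimated correlation. All 4 calls were lost with fry and without relA* uninduced replicate 1 (limma camera adjusted p from 0.0573 to 0.717). With the tRNA share as a covariate ribosomal proteins were called lower and the other 3 calls were lost. Ribosomal proteins also lost theirs without relA* replicate 0 or relA- replicates 1 or 2, and DNA replication without relA- replicates 1 or 2 or with only the compared groups. The ribosomal protein median was −0.0069 without relA- uninduced replicate 1, and −0.15 with the tRNA share as a covariate, a fit chosen after seeing the data.

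How far the strain difference before induction with the relA- plasmid resembled the relA* response of wild type was asked across the same 4201 genes, in comparisons with no shared library. The log2 changes had r = 0.218 (Spearman rho 0.152, and r = 0.281 over the 3049 genes of at least 20 CPM), and genes are not independent replicates. Other splits of the 6 baseline libraries gave correlations with a median size of 0.155 and up to 0.181. Of 91 genes that fell in wild type, 17 were lower in P153L, among them rpsU, where 0.931 are expected, and of 43 that rose 7 were higher, among them gnsB and rpoS, where 1.45 are expected. The 91 fallers had a median of −0.50 in P153L, with 81 of the same sign, and the 43 risers 0.27, with 30.

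The authors' deposited tables were set beside the edgeR results. For the relA* response the authors' deposited table held 32 genes higher and 87 lower in wild type, sharing 114 with edgeR (r = 0.998 of log2 changes, as for infA and rpsU), and for P153L the authors' deposited table held 10 and 171, sharing 175 (r = 0.996). For the relA- response the authors' deposited tables held 3 and 0 in wild type and 7 and 0 in P153L, and edgeR called all of these. For the relA*-specific part the authors' deposited tables held 8 and 29 in wild type (32 shared) and 1 and 80 in P153L (65 shared). For P153L against wild type with the relA- plasmid the authors' deposited table held 311 and 133, sharing 173 (r = 0.934). The log2 changes of that authors' deposited table had r = 0.999 with a DESeq2 strain effect over both induction states and r = 0.910 with uninduced libraries alone. An edgeR strain effect over both states called 295 higher and 124 lower and shared 181 of the 186 genes called before induction.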

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

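Among the tests of this part, the difference between the plasmid effects of the strains and the splits by which libraries they kept were chosen only after the result was seen. Each result here is a difference between 2 groups' effects under the same contrast that passed its own test. Groups of 3 were not tested for a library far from the others, and counts without each library in turn stand with the results.

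The relA* response of P153L minus that of wild type had 0 genes higher and 7 lower by edgeR, with 411 at an unadjusted p below 0.05 and 0 and 17 by DESeq2. Genes tmaR (−2.75), panD (−2.32), msrC (−2.22), gnsB (−1.93), ytfP (−1.93), aceB (−1.46) and alaS (−1.46) all lay lower in P153L. Of 10 lists called by camera, 9 lay lower, with medians of −0.51 for ribosomal proteins, −0.34 for aminoacyl-tRNA synthetases, −0.77 for branched-chain, −0.66 for threonine and lysine and −0.26 for glutamate to cysteine synthesis. The others were −0.48 for NADH dehydrogenase with cytochrome oxidases, −0.28 for fatty acid synthesis, −0.52 for heat shock and −0.53 for the sigma E regulon, against 0.24 for flagella and chemotaxis. All 10 calls were lost with an estimated correlation (camera of limma, adjusted p from 0.215 to 0.63).

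The relA* response minus the relA- response had 8 genes higher and 26 lower in wild type, led by raiA and pyrL, and 1 higher and 69 lower in P153L, mntS being the 1 and rpsU leading the 69. The strain difference with the relA* plasmid minus that with the relA- plasmid had 24 genes higher and 27 lower, led by ecnB (4.31 ± 0.89) and csrC (3.36 ± 0.44) and by fnrS (−4.59 ± 0.85) and racC (−3.46 ± 0.66). The calls of ecnB and racC were lost without at least 1 library.

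By the planned test chance stays a possible explanation for all 4 of these differences. That test counted the genes called under other splits of the same libraries, of which 100 of 200 were drawn for each. The share of splits that called as many genes was too large to exclude chance. As many genes were called in 15 splits for the strain difference (7 called, highest other 216), in 9 for the wild-type difference of responses (34, highest other 74), in 12 for that of P153L (70, highest other 386) and in 9 for the plasmid difference (51, highest other 119). The real split is included in each number. The other splits with as many genes, 14, 8, 11 and 8 of them, all kept the real labels in 1 of the 2 compared sets of 6 libraries, as 18 of the 100 splits did, so that 1 real effect stayed in the difference. No split that mixed the labels in both sets called as many. Splits that called several times the real count point to this structure of the samples. Sorting the splits by the labels they kept was chosen after the result was seen, so it does not overturn the planned test.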

How the results depend on the processing

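The tRNA share as a covariate, the fit without the library of the lowest total and every value of the 2 comparisons of uninduced P153L libraries were chosen only after the result was seen, as was the count of called lists. All other alternatives were planned, and each of them ran.

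Of 162 named calls by edgeR, 161 were kept with DESeq2 size factors, 162 without the low-count filter, 161 with rRNA and tRNA genes removed, 161 with the tRNA share as a covariate, 162 with the replicate block and 152 with only the compared groups. DESeq2 kept 154 of the 158 for which it gave an adjusted p, with none for tmaR, panD, msrC and ytfP in the strain difference. Of the 162, 113 were kept without each library in turn. None of these named calls reversed its direction under any of these, while some named genes without a call, such as dksA and uspA, changed sign. The all-gene median of a log2 change stayed within −0.03 to 0.04 under each scaling. The gene ytfP missed the edgeR threshold with DESeq2 size factors and with rRNA and tRNA genes removed, with an adjusted p up to 0.197 over its alternatives.

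DESeq2 called 10 genes higher in the P153L relA* response and 17 lower in the strain difference. With a log2 change of at least 1 in addition, there were 8 higher in the P153L relA* response, 28 lower in the P153L baseline (P153L against wild type, relA- plasmid, uninduced), 75 lower in that baseline with the relA* plasmid, and 94 higher and 90 lower between plasmids in uninduced P153L. These falls follow from the stricter rule. Without the low-count filter 2 genes were higher in the relA*-specific response of P153L. With only the compared groups in the fit there were 7 higher in the P153L relA* response and 23 higher in the relA*-specific response of wild type. The cause was not tested.

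With the replicate block, higher and lower calls numbered 110 and 166 in the wild-type relA* response, 61 and 328 in that of P153L, 23 and 131 in the strain difference, 59 and 98 in the relA*-specific response of wild type and 16 and 183 in that of P153L. Lower calls numbered 100 in the P153L baseline, 212 in that with the relA* plasmid and 2 in the wild-type relA- response, and the plasmid difference of the baseline had 44 and 49. Only the last of these single counts, the 2, and the 212 belong to comparisons whose replicate numbers paired the samples by the rule. In the other comparisons within a plasmid the tRNA share still followed the replicate number, so the block may remove shared spread there too.

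With the tRNA share as a covariate there were 149 lower in the wild-type relA* response, 60 and 355 in that of P153L, 4 and 109 in the strain difference, 223 and 117 in the P153L baseline and 346 and 224 in that with the relA* plasmid. There were 22 and 87 in the relA*-specific response of wild type, 18 and 204 in that of P153L, 72 and 50 in the plasmid difference of the baseline, and 1 lower between plasmids in wild type. The ribosomal protein median between plasmids in wild type turned to −0.15. The cause of these shifts was not tested.

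Lists called fell to 0 with an estimated correlation in the wild-type relA* response, the P153L relA* response, the strain difference and the P153L relA- response, and to 1 in the P153L baseline. With fry, a test of whether a list moves one way and not of lists against other genes, 5 were called in the wild-type relA* response, 5 in the strain difference, 1 in the P153L baseline and 0 in the P153L relA- response. It called 15 in the P153L relA* response, 0 in the relA*-specific response of wild type, 0 between plasmids in wild type and 2 in the plasmid difference of the baseline. In the other comparisons most list calls were lost with an estimated correlation too. As Spearman ranks the 2 correlations across genes were 0.176 between the relA* responses and 0.152 between the P153L baseline and the wild-type response, and the latter was 0.281 over genes of at least 20 CPM.

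Without each library in turn, ranges were 21 to 49 higher and 59 to 96 lower in the wild-type relA* response, 10 to 39 and 99 to 295 in that of P153L, and 0 to 7 and 1 to 97 in the strain difference. Lower calls were 16 to 50 in the P153L baseline, and 5 to 8 genes were higher in the P153L relA- response. The relA*-specific response had 0 to 11 higher and 10 to 50 lower in wild type, and 0 to 5 and 37 to 142 in P153L. The baseline with the relA* plasmid had 143 to 280 and 73 to 137. Between plasmids in uninduced P153L, 90 to 206 were higher, with 90 and 92 without relA* replicates 0 and 1 and 94 without relA- replicate 2. The plasmid difference of the baseline had 11 to 45 higher and 17 to 32 lower. Its higher calls numbered 11, 15 and 45 without P153L relA* replicates 0, 1 and 2, 13 without relA- replicate 2 of either strain, and 15 without wild-type relA* replicates 1 or 2, and its lower calls 17 without P153L relA* replicate 0. Other libraries that moved a count by more than 1.5 times are named beside the counts of the report.

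Called lists numbered 6 to 15 in the strain difference, 3 to 5 in the P153L baseline, 0 to 5 in the wild-type relA- response and 0 to 2 in that of P153L. The ribosomal protein median of the wild-type relA- response lay between −0.31 and 0.21, turning positive without wild-type relA- uninduced replicate 0, and that between plasmids in wild type between −0.0069 and 0.52, turning negative without relA- uninduced replicate 1. Each of these fits has fewer samples.

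The median protein-coding gene had 7 counts in the shallowest library and 78 in the deepest, and depth itself was not varied. In the simulation at these depths 22% of 2-fold changes were recovered for the strain difference, which is a difference of 2 responses, against 64% for the wild-type response alone. A gene that did not pass there is not shown to respond alike in both strains.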

Other observations

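All tests of explanations in this part were chosen only after the result was seen, except the splits of the samples. For the tRNA share the bound was set before the value of the test was known. Some were also revised after their values were known, as said beside them.

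Uninduced P153L libraries differed between the plasmids, a comparison added after the data were examined. With the relA* plasmid ecnB (4.18 ± 0.46, edgeR adjusted p = 8.13e-08), rmf (3.26 ± 0.38), csrC (3.15 ± 0.32), the leader leuL (2.78 ± 0.30), the bacterioferritin gene bfr (2.44 ± 0.38), ilvL (2.42 ± 0.32) and aceK of the glyoxylate bypass (2.37 ± 0.24) were highest. Lowest were fnrS (−4.09 ± 0.38, edgeR adjusted p = 6.16e-09), racC (−3.44 ± 0.30), ydaS (−2.99 ± 0.32), the lactate dehydrogenase gene ldhA (−2.62 ± 0.24), the small RNA micA (−1.99 ± 0.35), hslJ (−1.93 ± 0.25) and yebF (−1.91 ± 0.28). Both rpoS (1.03 ± 0.21, edgeR adjusted p = 0.00113) and thrA (0.83 ± 0.22, edgeR adjusted p = 0.0153) were higher. No call was made for relA (0.63 ± 0.32, edgeR adjusted p = 0.315), rpoB (−0.10 ± 0.29), dksA (0.33 ± 0.30) or spoT (0.09 ± 0.19). In all edgeR called 143 genes higher and 139 lower, and DESeq2 119 and 98, sharing 213. The genes thrA, uspA, uspD and cysK missed the edgeR threshold without at least 1 library, among them relA* replicate 0.

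As lists, 6 of 13 branched-chain synthesis genes were higher (8 adjusted over the list alone), with a median of 0.70 and leuB (1.87 ± 0.23), leuD (1.79 ± 0.28) and leuA (1.32 ± 0.21) among them, and limma camera adjusted p = 3.14e-06 (adjusted p = 0.0619 with an estimated correlation). Synthesis of glutamate, proline, serine and cysteine had 0.43 with 4 of 14 higher (5 adjusted over the list alone), among them serA (1.72 ± 0.21), serC (1.13 ± 0.22) and cysK (1.02 ± 0.22), and limma camera adjusted p = 0.000227 (adjusted p = 0.0832 with an estimated correlation). Of 15 threonine and lysine genes 5 were higher (6 adjusted over the list alone), with a median of 0.40 and thrB (1.19 ± 0.22), asd (1.02 ± 0.21) and thrC (0.94 ± 0.19) among them, and limma camera adjusted p = 0.00333 (adjusted p = 0.162 with an estimated correlation). Hibernation and universal stress genes had 0.76 with rmf, uspD (1.25 ± 0.36) and uspA (1.08 ± 0.30) higher of 10 and 1 lower (5 and 1 adjusted over the list alone), and limma camera adjusted p = 0.036 (adjusted p = 0.213 with an estimated correlation). The RpoS regulon had 0.31 with ecnB the 1 of 37 higher (1 adjusted over the list alone), and limma camera adjusted p = 0.0143 (adjusted p = 0.162 with an estimated correlation). The tricarboxylic acid cycle had 0.26 with gltA (1.16 ± 0.24) the 1 of 15 higher (1 adjusted over the list alone), and limma camera adjusted p = 0.0143 (adjusted p = 0.389 with an estimated correlation). Without relA* replicate 0 the calls of the RpoS regulon, the tricarboxylic acid cycle and hibernation were lost (limma camera adjusted p = 0.0551, 0.0815 and 0.18). Hibernation was also lost without relA- replicates 0 or 2 (limma camera adjusted p = 0.0642 and 0.0597) and with the replicate block. Of 7 lists called in the plasmid difference of the strain effect, 5 were lost without at least 1 library, and with an estimated correlation branched-chain synthesis held, with a median of 0.98 and 3 of 13 higher (8 adjusted over the list alone), leuD at 2.29 ± 0.45 (limma camera adjusted p = 1.87e-07, and adjusted p = 0.0302 with an estimated correlation).

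For this difference, relA* made before induction is a candidate explanation for the genes that rise. The 43 genes that rose in wild type after induction had a median of 0.85 between plasmids in uninduced P153L, 39 of them above 0, and with 70.3% of the wild-type response met a bound of 25%. For the 91 genes that fell it stays open, since they had −0.15, or 10.2% of the response, with 1 called lower, but 61 lay below 0, where the binomial limit from all genes is 53. Between plasmids in wild type the risers had −0.01 and the fallers 0.21 with 12 below 0, in libraries that the wild-type response shares, and these bounds were set and revised after the values were seen. The tRNA share argues against itself as the cause, since 282 of 282 genes stayed called with it as a covariate.

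The genes higher in uninduced P153L with the relA- plasmid lay close together, 76 of 142 within 500000 bases. Chance placement of blocks of 10 neighbouring genes is argued against for this window, since no shuffle of them reached 76 (10000 shuffles, highest 47, permutation p = 0.0001, the smallest they can give). Such blocks break up longer stretches of genes that vary together. No other block length was run, here or in the next test, so chance placement of longer stretches is not excluded. Extra copies of the stretch or another replication gradient are argued against as the whole cause, since with the local median of 51 neighbouring genes (up to 0.94) taken from each gene 54 of the 76 were still higher, and no shuffle reached 54 (highest 44, permutation p = 0.0001). They stay open for the others and for copies of shorter stretches. The mutation acting alike with either plasmid stays open, since the strain difference of 16 of the 76 genes, fnrS and racC among them, differed between the plasmids, which choosing them in the same libraries favours. For racC this call was not kept with each library left out in turn. The tests of copies and of the mutation replaced earlier ones after their values were seen.

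The rise of 7 genes besides relA in P153L with the relA- plasmid may come from reads of the induced plasmid transcript counted to them. For rlmD, ybeU and fdhF the gain in CPM per gain in relA CPM differed by at most 1.67 times between the 4 strain and plasmid combinations, within the bound of 2, although single combinations were up to 5.50 standard errors apart for rlmD and 2.81 for fdhF. For garL, entB, lptE and atpI it stays open, since with the relA- plasmid the strains were at most 1.81 standard errors apart and the lowest gains lay within 2 standard errors of 0. Over all 4 combinations the largest differences were 6.19 standard errors for atpI, 3.01 for entB and 2.60 for lptE, but with relA* a change of the chromosomal gene can hide plasmid reads, and this test was revised after the values were seen. A biological explanation was not tested here.

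For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 136 and 0 for the wild-type relA* response, 203 and 157 for that of P153L, 186 and 0 for the P153L baseline, 3 and 1 for the wild-type relA- response and 8 and 0 for that of P153L. They were 361 and 1 for the baseline with the relA* plasmid, 282 and 0 between plasmids in uninduced P153L, and 0 and 0 between plasmids in wild type, where all 10 gave as many. In each of the others 1 of 10, the real split, gave as many. The correlation of the P153L baseline with the wild-type relA* response was 0.218, and other splits of the baseline libraries had a median size of 0.155 and a largest of 0.181.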
